A study of Homo sapiens with 4 samples.

How the data were processed

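RNA from 4 derivatives of the human prostate cancer line PC-3 was measured on Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per line. Per the labels' protocols, cells were grown in dishes to near confluency, total RNA was column-purified and biotin-labelled target was hybridised. Groups were taken from the labels' telomere length: mock and mock/cre+ as short telomeres, LhTERTL and LhTERTL/cre+ as long telomeres, with the Cre and hTERT status of each line from its labels. The labels give no replicate numbers, and lines were matched only by Cre status.

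The authors deposited log2 values made with RMA (background correction, quantile normalization and probe set summary), per the submitters' processing notes; the software and version are not given in the sources used here. In the deposited table the median of every probe set over the 4 arrays was 0 within 1e-05, so each row had been centred and the level of expression is unknown; the scale was taken as log2 and higher values as higher expression. The median of each array's values was 0.01 for mock, -0.01 for mock/cre+ and 0.00 for both LhTERTL and LhTERTL/cre+, and their SDs were 0.209, 0.254, 0.335 and 0.179. The 2 deposited lists of probe sets, 124 higher and 129 lower, hold the same log2 values as the deposited series table, and their selection rule is not given in the sources used here; in the lower list the columns headed LhTERTL and mock/cre+ hold each other's values (100% of 129 probe sets, tolerance 1e-05), so only its probe set names were used.

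Of 54675 probe sets, 62 Affymetrix controls were left out of the tests. A platform annotation table paired 41091 of the 54613 remaining probe sets with 1 gene symbol and 1801 with several, and 11721 were unnamed here; 41037 were matched by Entrez number to a RefSeq gene table (assembly GRCh38.p14), which changed 0 symbols. That table was used only for names and gene order, and no coordinates are printed. Genes were summarised as the mean of their probe sets with 1 symbol (19775 genes, 10523 with several probe sets), and the probe set range is given where a named gene's probe sets disagree.

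Because the rows were centred, some choices fixed before the data were examined could not be run. A filter on mean log2 value of at least 5, with at least 7 or none as alternatives, needs levels, so all probe sets entered. A variance trend on the level has no meaning here, so limma's eBayes was run without a trend, and the trend on the centred mean was added as an alternative. The probe set of highest mean per gene could not be chosen, so the mean over probe sets was used. Random gene lists were matched on deciles of the SD over the 4 arrays in place of mean expression.

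The long and short groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment at 0.05, at the probe set and gene level; the same fit was made for the Cre split and for the remaining split of the 4 arrays. Gene list tests used camera with a preset inter-gene correlation of 0.01 on 30 lists fixed before the data were examined, with an estimated correlation and fry as alternatives. With both, 0 lists were called: the smallest adjusted p was 0.989 with the estimated correlation and 0.999 with fry. Fry asks whether a set's genes move one way and compares it with no other genes. Both rest on 2 residual degrees of freedom, whose spread holds the Cre and hTERT differences. The smallest unadjusted p with the estimated correlation (camera) was 0.0981, and the power was not simulated. A call lost with either therefore does not show that a list is unchanged. Counts in both Cre-matched pairs and the hTERT contrast are descriptions without a test. The deposited lists were compared with the 30 gene lists by one-sided Fisher's exact tests with Benjamini-Hochberg adjustment, among genes with a probe set at least 1.4-fold apart in both pairs in any directions. A value of ± is the moderated standard error of the difference between group means of 2 arrays each, unless it is given as over genes; where stated, the latter was widened by the square root of 1 plus the estimated correlation times the number of other genes in the list. The estimated correlation came from the spread within the telomere groups, so a shift shared by a list's genes between arrays of a group raises it. Simulated arrays with 200 changed genes or probe sets per fold size were used to check the fits before use. The list test called the 1 moved list and 0 of the others. Its simulated genes were independent, whereas estimated correlations in the real lists reached 0.84. That check therefore cannot show whether calls with the preset correlation are sound. On the real arrays the same test called 14 lists for the Cre split and 4 for the remaining split. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.

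Genes were named by a rule fixed before the data were examined: TERT; in each direction up to 12 genes with adjusted p under 0.05 and the same direction in both pairs, filled to 12 with genes at least 2-fold apart in both pairs; up to 4 members of each list with the largest absolute difference; and for hTERT the 6 highest and 6 lowest genes at least 2-fold apart in the long lines and under 0.5 in size in the control lines. No gene passed the adjusted threshold, and 2 genes higher and 5 lower met the fill rule. Names outside the rule are marked as chosen after their values were seen, or belong to the deposited lists. Alternatives were median-centred arrays, quantile normalization of the arrays, a robust prior and Cre status as a block. Others were an adjusted p of 0.1, other fold thresholds, another pairing and leaving out each array. Where that left 1 array in a group, it was assumed to vary like the other group. Leaving out an array also unmatched the groups by Cre status, so those values hold part of the Cre difference.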

Results

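Gene expression was measured on 4 oligonucleotide arrays, each hybridised with RNA from a derivative of PC-3, an established epithelial line from a human prostate cancer metastasis. Telomeres are the repeat-capped ends of chromosomes, and hTERT (gene TERT) is the catalytic subunit of telomerase, the enzyme that extends them. The short-telomere group held the control line named mock and its Cre-treated counterpart mock/cre+, both with basal hTERT. The long-telomere group held LhTERTL, which overexpressed hTERT, and LhTERTL/cre+, which kept long telomeres with basal hTERT after Cre, a recombinase that removes marked DNA. The series asks which genes differ between telomere-elongated and control cells, with and without the exogenous hTERT. Each of the 4 lines was measured on 1 array, so the 2 arrays of a group are different lines and p-values measure only the spread between these samples. The number of arrays limits the precision, and an exact permutation test of 2 against 2 arrays cannot go below p = 0.333 (two-sided). The deposited log2 values of each probe set were centred on its median over the 4 arrays, so differences between arrays are reported and no expression level can be.

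TERT itself was read first, as a check of the labels. The first of its 2 probe sets stood at 3.54 (log2) in LhTERTL, against 0.12 in mock, -0.12 in mock/cre+ and -0.16 in LhTERTL/cre+, so the array labelled as overexpressing hTERT was the one with the high value. The second TERT probe set went the other way, at -0.66 in LhTERTL and between -0.06 and 0.10 in the other 3 arrays. The part of the transcript each probe set reads was not given in the sources used here. Among the other genes of the telomerase and telomere protection list, STN1, a member of the complex that helps fill in the telomeric strand, differed by 0.32 ± 0.13 (long minus short, SE, n = 2 per group), and TINF2, a shelterin component, by 0.26 ± 0.13. RUVBL1, a helicase used in telomerase assembly, differed by -0.28 ± 0.16. None of the 21 measured members passed the test, and the list did not differ from other genes (limma camera, adjusted p = 0.983).

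**Figure D1:**
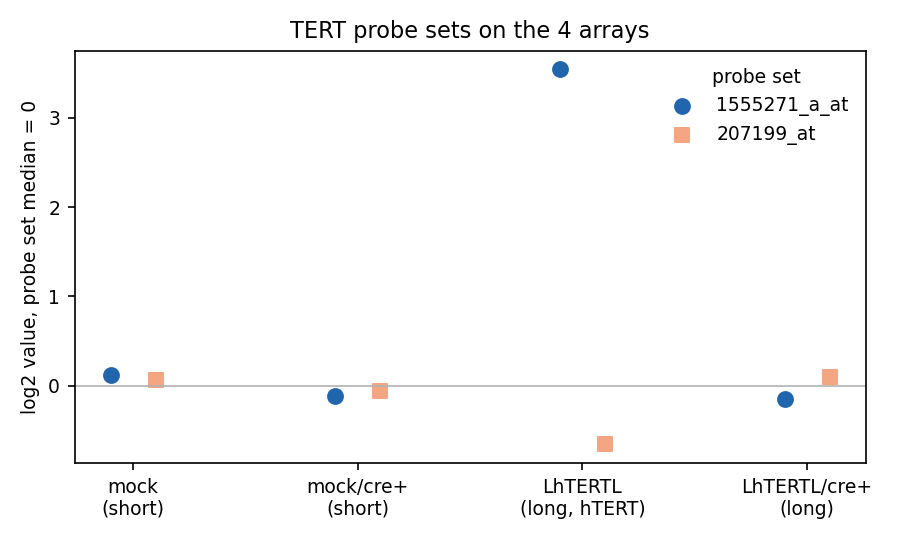
Log2 value of the 2 TERT probe sets (y axis, each centred on its median over the arrays) on the 4 arrays (x axis), 1 point per array and probe set. The first probe set reached 3.54 in LhTERTL and lay between -0.16 and 0.12 in the other arrays.

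Long-telomere cells were compared with short-telomere cells over all 4 arrays to ask which transcripts follow telomere length. The long non-coding RNA LINC01133 was higher in both Cre-matched pairs, by 1.34 in LhTERTL over mock and by 1.59 in LhTERTL/cre+ over mock/cre+; its mean difference was 1.47 ± 0.13 (SE, n = 2 per group), with its probe sets apart at 0.31 and 2.63. WIPI1, a phosphoinositide-binding protein of autophagosome formation, was 1.18 and 1.15 higher. Lower in both pairs were HSD17B2, which oxidises estradiol and testosterone, at -1.31 and -1.80, S100A9, a calcium-binding protein of inflammation, at -1.17 and -1.28, and PLAT, tissue plasminogen activator, at -2.70 and -1.15. SPARC, a secreted matrix protein, stood at -1.72 and -1.14, and UHRF1, which maintains DNA methylation at replication forks, at -1.16 and -1.10. These 7 genes are all those at least 2-fold apart in one direction in both pairs, and they are given by value because none passed the test. The groups overlapped for 3 of them, since LhTERTL/cre+ stood at 0.73 (UHRF1), 0.21 (SPARC) and -0.43 (WIPI1) relative to mock.

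No probe set was called higher and none lower among 54613 tested (limma, two-sided, Benjamini-Hochberg adjusted; smallest adjusted p = 0.905, for a LINC01133 probe set). At an unadjusted p under 0.05 (limma) there were 350 higher and 345 lower probe sets, together 695 where 2730.65 would be reached by chance. At the gene level there were 156 of 19775 genes against 988.75. The error term of this fit holds the Cre and hTERT differences within the groups, and larger ones lower these counts. On simulated arrays with the spread of these samples, the probe-level test recovered 0% of 4-fold and 80.5% of 8-fold changes, and the gene-level test 0% of 2-fold and 71.0% of 4-fold changes. The telomere split was also the smallest of the 3 ways to part the arrays 2 against 2, with a root mean square difference of 0.222 against 0.290 for Cre status and 0.318 for LhTERTL with mock/cre+ against mock with LhTERTL/cre+.

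Cell cycle genes were lower in the long-telomere arrays of each Cre-matched pair. The G1/S list averaged -0.54 over 29 genes, 24 of them lower in both pairs, and the G2/M list -0.32 over 30 genes, 25 of them lower in both (camera with a preset correlation of 0.01, adjusted p = 9.39e-07 for each list, and adjusted p = 0.989 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, differed by -1.13 ± 0.89 (SE, n = 2 per group), CCNE2, cyclin E2, by -1.08 ± 0.99 and CDT1, which licenses replication origins, by -0.85 ± 0.67. In the G2/M list CCNA2, cyclin A2, differed by -0.72 ± 0.38, KIF20A, a mitotic kinesin, by -0.57 ± 0.53, NUSAP1 by -0.51 ± 0.30 and CDK1 by -0.50 ± 0.52. No member of either list passed the test over all genes or adjusted over the list alone. In G1/S the 2 arrays of a telomere group lay further apart than the group means did. LhTERTL minus LhTERTL/cre+ was -1.01, and mock/cre+ was 0.86 above mock. Across the groups, the long-telomere line LhTERTL/cre+ was 0.40 above the short-telomere line mock. Without mock/cre+ the G1/S difference was -0.10, and without LhTERTL it was -0.03. The G2/M difference was -0.05 without mock/cre+ and -0.03 without LhTERTL. Without mock or LhTERTL/cre+ the differences were larger, at -0.97 and -1.04 for G1/S and -0.59 and -0.61 for G2/M. All these values hold part of the Cre difference, since the groups were then no longer matched by Cre status. In the matched pairs without and with Cre, G1/S stood at -0.61 and -0.46 and G2/M at -0.34 and -0.30.

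Interferon-stimulated genes were lower in the long-telomere arrays, with a mean of -0.25 over 48 genes, 38 of them lower on average and 21 lower in both pairs (camera, adjusted p = 9.39e-07; adjusted p = 0.989 with an estimated correlation). IFIT1, an antiviral RNA-binding protein, differed by -1.09 ± 0.34 (SE, n = 2 per group), with -0.77 and -1.41 in the pairs without and with Cre. IFI44 differed by -0.92 ± 0.41, OASL by -0.82 ± 0.33, and HERC5, the ligase that attaches ISG15, by -0.82 ± 0.50, with 0.17 and -1.80 in the 2 pairs. In 15 of the 48 genes both long arrays lay below both short arrays (31.2%, against 11.7% of all genes and 16.7% by chance), and in 1 both lay above. No member passed the test over all genes or adjusted over the list alone. The mean stayed below 0 without any single array, between -0.11 and -0.39, and lost the call without mock/cre+ (adjusted p = 0.383).

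Stress response genes were higher. The unfolded protein and amino acid stress list averaged 0.53 over 28 genes, 27 of them higher on average and 13 in both pairs (camera, adjusted p = 9.39e-07; adjusted p = 0.989 with an estimated correlation). DNAJB9 and HSPA5, chaperones of the endoplasmic reticulum, differed by 1.20 ± 0.85 and 0.99 ± 0.73 (SE, n = 2 per group), SDF2L1 by 1.08 ± 0.62 and DDIT3, the stress transcription factor CHOP, by 1.02 ± 0.94. The difference was 0.21 in the pair without Cre and 0.86 in the pair with Cre. The list mean of mock/cre+ was -1.05 relative to mock. Without that array the difference was 0.01, in groups no longer matched by Cre status. The oxidative stress list averaged 0.41 over 21 genes (adjusted p = 0.0105; adjusted p = 0.989 with an estimated correlation), with 0.93 in the pair without Cre and -0.12 in the pair with Cre. Its leading members were AKR1C3, an aldo-keto reductase, at 3.54 and -0.59 in the 2 pairs, and HMOX1, heme oxygenase 1, at 1.94 and 0.65. AKR1C2 stood at 3.04 and -0.63 and AKR1C1 at 1.90 and -0.27. The 5 probe sets of AKR1C1 disagreed, with long minus short differences from -0.09 to 1.94. The oxidative stress list lost its call without LhTERTL (-0.08, adjusted p = 0.814), without mock (0.37, adjusted p = 0.113) and without mock/cre+ (0.45, adjusted p = 0.383), and stood at 0.89 without LhTERTL/cre+. The unfolded protein list stood between 0.01 and 1.06 without single arrays. No member of either list passed the test over all genes or adjusted over the list alone.

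**Figure D2:**
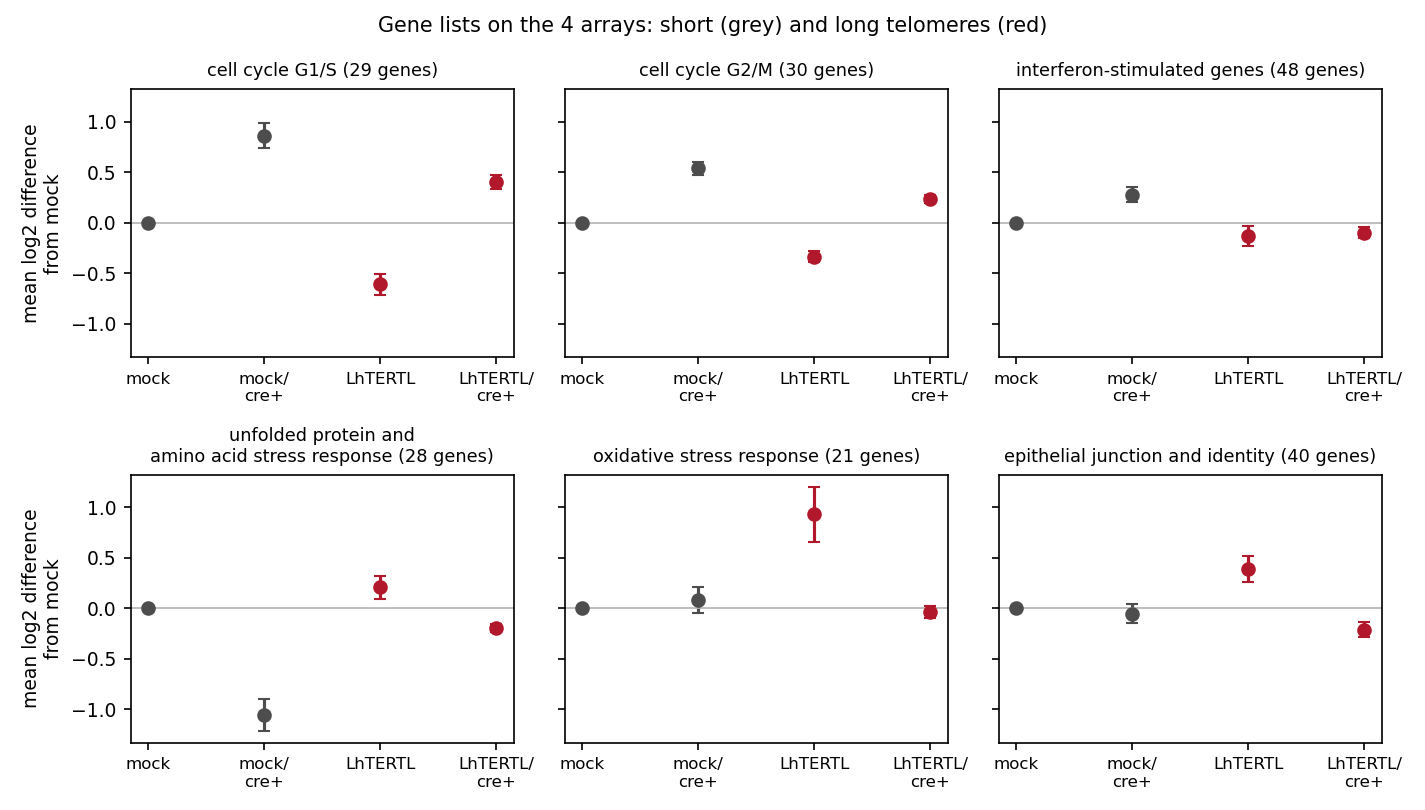
Mean log2 difference from mock (y axis) of 6 gene lists on the 4 arrays (x axis), short-telomere lines in grey and long-telomere lines in red. Points are means over the genes of a list and bars the standard error over genes, with 1 array per line. The G1/S mean was 0.86 in mock/cre+, -0.61 in LhTERTL and 0.40 in LhTERTL/cre+, and the interferon mean was 0.28, -0.13 and -0.10.

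Of the other lists, 4 were called with the preset correlation and lost the call with an estimated one (adjusted p = 0.989 for each with an estimated correlation). MYC and ribosome biogenesis genes averaged -0.22 over 20 genes, all 20 lower on average (adjusted p = 1.13e-05), with MYC at -0.55 ± 0.35 (SE, n = 2 per group), the nucleolar protein UTP20 at -0.49 ± 0.26, ODC1, which starts polyamine synthesis, at -0.47 ± 0.27 and NOLC1 at -0.40 ± 0.28. The list of ALT (recombination-based telomere upkeep) and telomeric chromatin averaged -0.17 (adjusted p = 0.0139), with the histone H3 lysine 9 methyltransferases SUV39H2 at -0.62 ± 0.50 and SUV39H1 at -0.49 ± 0.27, HNRNPA1 at -0.47 ± 0.17 and the helicase BLM at -0.46 ± 0.48. DNA damage response and repair genes averaged -0.15 (adjusted p = 0.0485), led by the exonuclease EXO1 at -0.88 ± 0.58, with FANCI at -0.45 ± 0.51 and the ligase LIG4 at 0.35 ± 0.19. Cholesterol and fatty acid synthesis genes averaged 0.16 (adjusted p = 0.0475), with STARD4, a sterol carrier, at 0.82 ± 0.50 and SCD, stearoyl-CoA desaturase, at 0.67 ± 0.63. In the pairs without and with Cre the cholesterol list went opposite ways, at 0.38 and -0.07, with SCD at 1.53 and -0.19. The MYC list stood at -0.37 and -0.07, with 12 of its 20 genes lower in both pairs. The ALT list stood at -0.13 and -0.22 and the repair list at -0.17 and -0.14. No member of these 4 lists passed the test over all genes or adjusted over the list alone. Without mock/cre+ none of the 4 was called, with adjusted p = 0.152 for the MYC list, adjusted p = 0.963 for the ALT list, adjusted p = 0.797 for the repair list and adjusted p = 0.439 for the cholesterol list. The repair mean was then 0.01, and without LhTERTL the repair mean was 0.03 (adjusted p = 0.814) and the cholesterol mean -0.11 (adjusted p = 0.0112). The MYC list, at -0.04 (adjusted p = 0.722), and the ALT list, at -0.05 (adjusted p = 0.756), were not called without LhTERTL either. The cholesterol list also lost its call without mock (0.21, adjusted p = 0.118), and without LhTERTL/cre+ it stood at 0.43 and the MYC list at -0.40. With the probe set of highest SD per gene the repair list lost its call (adjusted p = 0.0882).

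The other 20 lists with a mixed or small difference were not called. Epithelial junction genes averaged 0.11 (adjusted p = 0.880), at 0.39 in the pair without Cre and -0.16 in the pair with Cre, and their leading members CLDN7, a tight junction claudin, at 2.72 and 0.33, CD24 at 2.79 and -0.87 and OCLN, occludin, at 1.76 and 0.12 were highest in LhTERTL. ELF3, an epithelial transcription factor, differed by 0.60 ± 0.67 (SE, n = 2 per group). Mesenchymal genes averaged -0.12 (adjusted p = 0.605), with CCN2 at -0.73 and -0.76 and NT5E at -0.54 and -0.72 in the 2 pairs; without mock the list was called lower at -0.29 (adjusted p = 0.0116). Matrix genes averaged 0.02 (adjusted p = 0.605) with COL5A1 at 0.74 ± 0.49 and COL5A2 at -0.78 ± 0.67 (SE, n = 2 per group), and integrins -0.02 (adjusted p = 0.983) with ITGA2 at -0.60 ± 0.31. Cancer stem cell related genes averaged -0.03 (adjusted p = 0.1996), with SOX9 at -0.68 ± 0.30 and ALDH1A1, a retinaldehyde dehydrogenase, at 4.55 and -1.25 in the 2 pairs; without LhTERTL the list was called lower at -0.25 (adjusted p = 0.00234). Inflammatory genes averaged 0.01 (adjusted p = 0.983), with IL1B at 0.85 ± 0.96 and LIF at -0.64 ± 0.34. The p53 target list averaged 0.16 (adjusted p = 0.250), with the cell cycle inhibitor CDKN1A at 0.99 ± 0.90. The TGF-beta and BMP list averaged -0.16 (adjusted p = 0.133) with ID3 at -0.77 ± 0.62, WNT genes -0.09 (adjusted p = 0.605) with CCND1 at -0.64 ± 0.26, and hypoxia and glycolysis genes 0.02 (adjusted p = 0.983) with VEGFA at 0.63 ± 0.50. Without mock the TGF-beta and WNT lists were called lower, at -0.29 (adjusted p = 0.0104) and -0.27 (adjusted p = 0.0317), and without mock/cre+ they stood at -0.02 and 0.08. The epithelial list was called lower without LhTERTL (-0.19, adjusted p = 1.63e-05) and higher without LhTERTL/cre+ (0.42, adjusted p = 6.01e-05), and the matrix list higher without mock/cre+ (0.18, adjusted p = 0.00154).

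Genes reported as sensitive to telomere length, a list of 6 measured members, averaged -0.06 (adjusted p = 0.379), with ISG15 at -0.42 ± 0.17, C1S at -0.31 ± 0.30 and DSP at -0.31 ± 0.33 (SE, n = 2 per group). TERT, overexpressed in LhTERTL, is also a member and raised the mean, at 0.71 ± 0.52, with 1.35 and 0.06 in the 2 pairs. Its probe sets stood at -0.28 and 1.69. The list without TERT was not tested, and the list median was -0.19. The list mean depended on single arrays and on the probe set chosen, at -0.22 without LhTERTL, 0.09 without LhTERTL/cre+ and 0.09 with the probe set of highest SD (adjusted p = 0.603). Prostate luminal markers averaged 0.04 (adjusted p = 0.660) with STEAP1 at 0.61 ± 0.39, prostate basal markers -0.05 (adjusted p = 0.983) with KRT15 at -0.98 ± 0.52, and neuroendocrine markers -0.00 (adjusted p = 0.983) with DDC at 0.22 ± 0.21. Markers of cells that a pure epithelial line should lack differed little between long and short arrays. Leukocyte markers averaged -0.03 (camera, adjusted p = 0.781), fibroblast markers -0.00 (adjusted p = 0.983) and endothelial markers -0.09 (adjusted p = 0.605). Without expression levels, these differences cannot show whether such cells were present. Antigen presentation genes averaged -0.01 (camera, adjusted p = 0.983) with HLA-DMA at 0.67 and -1.52 in the 2 pairs. Immediate early genes averaged -0.00 (adjusted p = 0.983) with FOS at 0.47 ± 0.23. Housekeeping genes averaged -0.06 (adjusted p = 0.740) with PGK1 at -0.31 ± 0.29, its 6 probe sets running from -0.64 to 0.02. Without LhTERTL the antigen presentation list was called lower at -0.16 (adjusted p = 0.0297). Median and mean differed in sign for the telomerase, integrin, prostate basal, neuroendocrine, WNT and antigen presentation lists.

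The 2 Cre-matched pairs were set side by side to ask which probe sets differ in both. At least 2-fold in both pairs, 7 probe sets were higher and 9 lower with long telomeres, where independent pairs would give 4.95 and 5.94. Against these 16 stood 361 probe sets at least 2-fold apart in opposite directions, 322 of them higher in LhTERTL than mock and lower in LhTERTL/cre+ than mock/cre+. Across probe sets the pair differences correlated at r = -0.356 (Spearman's rho = -0.184); probe sets are not independent replicates. The higher ones, beside LINC01133 and WIPI1, included SEL1L, which acts in the degradation of misfolded proteins, at 1.25 and 1.20. AGR2, a disulfide isomerase of secretory epithelia, stood at 1.12 and 1.81 and SLITRK6 at 1.70 and 1.06. The lower ones included CDCA7, a chromatin regulator, at -1.73 and -1.26 and a single IFI44 probe set at -1.32 and -1.61. MAP2K6, a p38 kinase activator, stood at -1.07 and -1.04. These names were chosen after their values were seen. The long and short arrays overlapped for AGR2, SLITRK6, CDCA7 and MAP2K6, and not for SEL1L and the IFI44 probe set.

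The deposited lists held probe sets of 91 genes given as higher and of 103 genes given as lower. Their probe sets were all higher or all lower in both Cre-matched pairs, with a smallest pair difference of 1.4-fold, and none of them passed the test, although 26 and 34 had an unadjusted p under 0.05 (limma). Both long arrays lay above both short arrays for 54 of the higher probe sets, and below for 56 of the lower ones. The difference by Cre was larger than that by telomeres for 70 of the higher and 73 of the lower probe sets, with median Cre minus no Cre differences of -0.83 and 0.85 beside median long minus short differences of 0.73 and -0.69. All lie within the 186 probe sets that were 1.4-fold higher and the 207 that were 1.4-fold lower in both pairs, counts that independent pairs would put at 160.8 and 202.5. Among the 1462 genes with a probe set at least 1.4-fold apart in both pairs in any directions, the lower list held 8 of 14 G1/S genes (CCND1, GINS2, MCM2, MCM5, MCM6, MCM7, RRM2 and UHRF1; one-sided Fisher's exact test, adjusted p = 5.89e-05 over 60 tests), 3 of 3 G2/M genes (CCNA2, CDK1 and NUSAP1; adjusted p = 0.00510) and 4 of 6 mesenchymal genes (CCN2, CDH11, NT5E and SPARC; adjusted p = 0.00510). It held 4 of 11 interferon-stimulated genes, DDX60, IFI6, IFIT1 and OAS3 (adjusted p = 0.0626). The higher list held 6 of 10 genes of the unfolded protein and amino acid stress list, the endoplasmic reticulum proteins CALR, DNAJC3, PDIA4 and PDIA6 with STC2 and TRIB3 (adjusted p = 0.000255). The lists were chosen by the authors on these samples, so they are not independent evidence of direction, and genes are not replicates in this test. In the deposited lower list the columns headed LhTERTL and mock/cre+ hold each other's values of the series table, so only its probe set names were used.

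**Figure D3:**
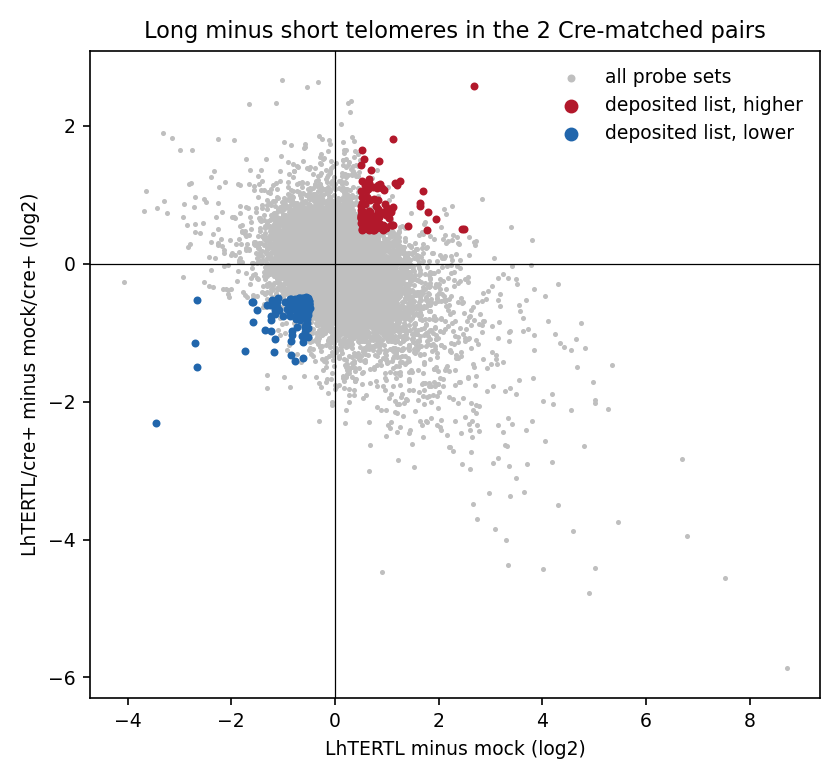
Difference of LhTERTL from mock (x axis, log2) and of LhTERTL/cre+ from mock/cre+ (y axis, log2) for 54613 probe sets in grey, with the deposited higher (red) and lower (blue) lists. The cloud runs from upper left to lower right (r = -0.356), and the deposited probe sets lie in the 2 quadrants where both pairs agree.

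Arrays of Cre-treated lines were compared with those of untreated lines as the other labelled split. Of the named G1/S genes, UHRF1 stood at -1.83 in mock minus mock/cre+ and -1.89 in LhTERTL minus LhTERTL/cre+, CCNE2 at -1.58 and -2.40 and RRM2 at -1.03 and -2.36, all lower without Cre. Also lower without Cre were NT5E, of the mesenchymal list, at -1.53 and -1.35 and the cytokine IL1B at -1.32 and -2.45. WIPI1 was higher without Cre, by 1.58 and 1.61, as were STARD4, by 1.03 and 0.97, and CDKN1A, by 0.92 and 2.43. As Cre minus no Cre, the G1/S list averaged 0.94, the G2/M list 0.56, the repair list 0.36 and the mesenchymal list 0.29, and the unfolded protein and amino acid stress list averaged -0.73 (camera calls; adjusted p = 0.473 with an estimated correlation for each). The preset correlation called 10 lists higher and 4 lower, none of which kept the call with an estimated correlation. No probe set passed (limma, adjusted p from 0.789 upward), with 3347 at an unadjusted p under 0.05. In the long-telomere lines Cre goes with the loss of exogenous hTERT, and the 2 effects cannot be told apart there.

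Exogenous hTERT was examined as LhTERTL minus LhTERTL/cre+, with mock minus mock/cre+ as the Cre control; each is 1 array against 1, with no replicate check and no test. Among genes under 0.5 in size in the control difference, 194 were at least 2-fold higher and 138 at least 2-fold lower in LhTERTL. After quantile normalization of the arrays the higher count was 112, below the lower count, so the excess of higher genes was not kept. The highest were LCN2, lipocalin 2, at 5.01, PLAC8 at 4.61, the cytokine IL6 at 3.87, INHBE, an inhibin beta subunit, at 3.49, BEX2 at 3.38 and SLAMF7 at 3.18. The lowest were the pseudogene AADACP1 at -3.60, the interferon-inducible kinase CMPK2 at -3.35, PLCXD3 at -3.26, PABPC5 at -3.09, NAP1L3 at -3.01 and the complement component C5 at -2.83. Before that restriction, 452 genes were 2-fold higher and 300 lower in LhTERTL, beside 128 and 400 in the control difference.

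For exogenous hTERT the gene lists were placed by the percentile of their median difference among 10000 lists drawn at random with the same spread over the arrays. Oxidative stress genes had a median of 0.73 in LhTERTL minus LhTERTL/cre+ and -0.06 in the control difference (percentiles 100.0 and 50.4), cholesterol and fatty acid genes 0.46 and 0.08 (percentiles 100.0 and 76.5), epithelial junction genes 0.48 and 0.08 (percentiles 100.0 and 91.1), and antigen presentation genes 0.28 and -0.18 (percentiles 99.98 and 0.74). Antigen presentation genes were not raised in LhTERTL alone, since relative to mock they averaged 0.26 in LhTERTL, 0.23 in mock/cre+ and -0.05 in LhTERTL/cre+. MYC and ribosome biogenesis genes had a median of -0.37, against -0.03 in the control difference. G1/S genes were low in both differences, at -1.18 and -0.76, and unfolded protein and amino acid stress genes were high in both, at 0.50 and 1.16. AKR1C3 stood at 3.04 in LhTERTL minus LhTERTL/cre+ and -1.09 in the control difference, HMOX1 at 2.08 and 0.79, CLDN7 at 1.91 and -0.48 and SCD at 1.81 and 0.09. These percentiles describe these 4 arrays only. The random lists held genes drawn independently, whereas genes of a list can move together, so an extreme percentile is not a test. Extreme percentiles also arose in the control difference, where both lines have basal hTERT. They were 0 for mesenchymal, 0.08 for matrix, 0.16 for G1/S and 100 for unfolded protein and amino acid stress genes.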

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

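The tests of explanations given here were all chosen after the result was seen. A difference within a single pair was not tested, since each pair is 1 array against 1; the difference between the pairs was fitted only as the crossed split of the 4 arrays, where no gene passed (smallest adjusted p = 0.134) and 1 probe set did.

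The difference between long and short telomeres went opposite ways in the 2 Cre-matched pairs for 361 probe sets that were at least 2-fold apart in each. Among the named genes, the values without and with Cre were 4.55 and -1.25 for ALDH1A1, 2.38 and -1.71 for IL6, 3.36 and -1.12 for PLAC8, 1.04 and -1.86 for EFEMP1, an extracellular matrix fibulin, and -2.11 and 1.18 for C5. The most extreme genes, chosen after their values were seen, were CYP1B1, a cytochrome P450 that oxidises estradiol and xenobiotics, at 5.77 and -3.59, the transcription factor ZIC2 at 5.47 and -3.74, RAI2 at 4.60 and -3.87, RTN1, a reticulon, at 4.11 and -3.71, CSTA, a cysteine protease inhibitor, at 3.34 and -4.37 and COXFA4L3 at 3.08 and -3.85. All 6 were high in LhTERTL and mock/cre+ and low in mock and LhTERTL/cre+.

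Those 2 arrays stood apart from the other 2 more clearly than the telomere groups did. A gap of at least 4-fold with both arrays of one side above both of the other was found for 49 probe sets in this crossed split, all higher in LhTERTL and mock/cre+, for 2 in the telomere split (LINC01133 and a probe set unnamed here, at -3.46 and -2.32 in the 2 pairs) and for 2 in the Cre split. An RTN1 probe set was the 1 probe set that limma called in any of the 3 splits (crossed difference 4.84 ± 0.11 SE, adjusted p = 0.0282), with 4000 at an unadjusted p under 0.05. Over all probe sets the 2 were not alike: LhTERTL and mock/cre+ were at least 2-fold apart at 2307 probe sets, the most of the 6 pairs of arrays, and mock and LhTERTL/cre+ at 294, the fewest. Quantile normalization of the centred values left the correlation of the pair differences at -0.383, so the correlation did not rest on their unequal spread. Unequal distributions before centring cannot be tested on these values. The 3' minus 5' signal of 6 control transcripts had a crossed difference of 0.0483 ± 0.0343 (SE over transcripts) against 0.130 expected for a mean of 6 probe sets, too close to decide on unequal amplification length, which stays open. An exchange of the labels of the 2 Cre arrays cannot be told apart from a real likeness of mock and LhTERTL/cre+: either gives the 49 probe sets, TERT marks neither Cre array, and the Cre control probe sets carry the Cre transcript added to every array (values between -0.09 and 0.04). If the labels had been exchanged, the telomere comparison would be the crossed one, in which the interferon list averages 0.12 in place of -0.25, the unfolded protein list -0.33 in place of 0.53, the G1/S list -0.07 in place of -0.54 and the G2/M list -0.02 in place of -0.32, none of the 4 called. The epithelial (0.28), WNT (0.26), antigen presentation (0.27) and cholesterol (0.22) lists would then be called higher, each lost with an estimated correlation (adjusted p = 0.978), and the hTERT contrast would set LhTERTL against the array now named mock/cre+.

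G1/S genes ordered the 4 arrays as mock/cre+, LhTERTL/cre+, mock and LhTERTL from high to low. Relative to mock, LhTERTL/cre+ lay at 0.40 ± 0.31 and mock/cre+ at 0.86 ± 0.54 (SE over 29 genes, widened for their estimated correlation, 1 array each), too uncertain to decide on telomere status or on exogenous hTERT as the whole cause. The estimated correlation came from differences within the telomere groups, mock/cre+ minus mock among them. A shift shared by the G1/S genes there widens its own standard error, so this comparison could hardly decide. Both of these lines have basal hTERT, so exogenous hTERT alone would give no difference between them. The 3' minus 5' signal of GAPDH and ACTB differed by at most 0.0269 between mock/cre+ and LhTERTL, far less than the G1/S difference of 1.47, which speaks against RNA degradation. G2/M genes gave the same order, with LhTERTL/cre+ at 0.24 ± 0.21 above mock. A difference in the share of cycling cells could not be decided on either and stays open with the others. The 2 Cre arrays were the highest in both lists. In G1/S, mock minus mock/cre+ averaged -0.86 and LhTERTL minus LhTERTL/cre+ -1.01, beside -0.61 and -0.46 for long minus short in the 2 pairs. Cre status acting beside telomere status would give the same order. The crossed split, which measures the departure from 2 such added differences, averaged -0.07 for G1/S and -0.02 for G2/M. With Cre status as a block both lists kept their call with the preset correlation, and an estimated one was not run there. With 1 array per line, neither difference can be told apart from variation between lines. The repair list gave the order of the G1/S genes and the unfolded protein list its reverse, while the oxidative stress list averaged 0.93 in LhTERTL, 0.08 in mock/cre+ and -0.04 in LhTERTL/cre+ relative to mock.

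Interferon-stimulated genes were lower in both pairs on average. From their slope on the G1/S list between LhTERTL and mock/cre+, LhTERTL/cre+ would lie 0.11 above mock, and it lay at -0.10 ± 0.12 (SE over 48 genes, widened for their estimated correlation, 1 array each), too uncertain to decide whether they follow the order of the G1/S genes. Telomere length, line-to-line variation and the possible exchange of labels stay untested for them. Among the controls, 24 poly-A spike-in probe sets averaged 0.33 in mock, 0.10 in mock/cre+, -0.18 in LhTERTL and -0.13 in LhTERTL/cre+, and 18 hybridization spike-in probe sets 0.06, 0.05, -0.02 and -0.10, so both kinds were lower in the long-telomere arrays, by value. The long minus short difference was -0.37 for poly-A and -0.11 for hybridization spike-ins. The poly-A difference was -0.14 in the crossed split and -0.09 by Cre. Its size along the telomere split exceeded that of the interferon list, at -0.25. Whether array processing differed between the telomere groups and added to their differences was not tested.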

How the results depend on the processing

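The alternatives with 1.4-fold, the centred-mean trend, the probe set of highest SD, probe sets with 1 symbol, median-centred arrays for the deposited lists, and the list tests of the 2 other splits were chosen after seeing the data; the filters on low values (none, and mean of at least 7) were not run because no level is kept. The calls of 0 higher and 0 lower probe sets, for telomere status and for Cre, were 0 in all alternatives run, in a design where the simulated 4-fold changes were not recovered at the probe level. With Cre status as a replicate block the telomere fit again called 0 probe sets, 0 of the deposited ones, and 3 lists higher and 6 lower. Counts in both pairs followed the fold threshold: 186 higher and 207 lower at 1.4-fold, 84 and 99 at 1.5-fold, and 1 and 1 at 3-fold. Pairing lines of opposite Cre status gave 10 higher and 3 lower in place of 7 and 9; the cause was not tested. For exogenous hTERT, 3-fold gave 63 higher and 32 lower genes, and quantile normalization gave 112 higher in place of 194, fewer than the genes lower in that alternative, so the excess of higher genes turned; the cause was not tested. The 3 lists higher and 6 lower became 0 and 0 with an estimated correlation and 0 and 0 with fry. Both of those tests rest on 2 residual degrees of freedom. The probe set of highest SD per gene gave 3 and 5, losing the repair list (camera, adjusted p = 0.0882). Leaving out each array gave between 1 and 4 lists higher and between 0 and 9 lower, the 0 without mock/cre+, where only the matrix list was called (higher, 0.18, adjusted p = 0.00154). Lists not called with all arrays gained a call without mock (mesenchymal -0.288, WNT -0.271, TGF-beta -0.291), without LhTERTL (cancer stem cell -0.246, telomere-sensitive genes -0.216, antigen presentation -0.164) or without LhTERTL/cre+ (epithelial 0.416). Leaving out another array changed the sign of many of these, such as the mesenchymal (0.0509) and WNT (0.0821) lists without mock/cre+ and the cancer stem cell list (0.179) without LhTERTL/cre+. Among lists called with all arrays or after the turn, 4 changed sign without LhTERTL: lowest and highest means over the arrays left out were -0.187 (adjusted p = 1.63e-05) and 0.416 for the epithelial list, -0.344 and 0.0342 for the repair list, -0.114 and 0.428 for the cholesterol list and -0.0784 and 0.891 for the oxidative stress list. The repair list also turned without mock/cre+, at 0.0146. Each fit without 1 array also unbalanced Cre status between the groups. Dependence on that array and on Cre cannot be told apart there. Named genes changed sign in 83 alternative values and kept it in 1105, none of them past a threshold. Array signal over background is not in the deposited values, so dim probe sets could not be set apart.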

Other observations

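Among the genes with the largest differences in both pairs, named here after their values were seen, those higher included ERO1B, an endoplasmic reticulum oxidase, at 0.97 and 1.24 in the pairs without and with Cre, CRELD2, an endoplasmic reticulum stress protein, at 0.74 and 1.11, and the peptidyl-prolyl isomerase FKBP14 at 0.72 and 0.77. The serotonin receptor HTR2B stood at 2.83 and 0.93, TFF3, a trefoil peptide of mucosal epithelia, at 1.64 and 0.88 and SLC46A3, a lysosomal transporter, at 0.81 and 1.36. Among those lower in both pairs were E2F8 at -1.35 and -0.96, ZNF367 at -1.59 and -0.85 and ORC1 at -0.74 and -0.79, the urea transporter SLC14A1 at -0.91 and -1.14 and BCHE, butyrylcholinesterase, at -1.06 and -0.79. None passed the test. E2F8, ZNF367 and ORC1 were higher in LhTERTL/cre+ than in mock, by 0.51, 0.91 and 0.66, and ERO1B, CRELD2 and FKBP14 stood at -0.23, -0.26 and -0.23 there, so for these 6 genes the telomere groups overlapped and the differences by Cre, such as -1.47, -1.75 and -1.45 in mock minus mock/cre+ for the first 3, were larger.

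Over all 19775 genes, both long arrays lay above both short arrays in 11.4% and below in 11.7%, each less than the 16.7% that chance gives.

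A hypothesis set before its result was seen was that long telomeres lower the genes nearest the chromosome ends. The 20 outermost protein-coding genes of each arm, by gene order and without the short arms of the acrocentric chromosomes, gave 620 measured genes. Their median long minus short difference was -0.01, at percentile 31.2 of random lists of the same size and spread, with percentile 0.61 in the pair without Cre and 86.8 in the pair with Cre. The values speak against a common lowering of these genes in both pairs. With the 50 outermost genes the percentile was 0.22 for the mean, 0.03 without Cre and 77.3 with Cre, so the low value came from the pair with LhTERTL alone.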
